A study of Homo sapiens with 6 samples.

How the data were processed

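Total RNA from PC3 cultures was hybridised to the nCounter PanCancer IO 360 panel, per the labels' protocols, and 6 libraries were analysed: empty vector (EV) or BTN1A1 vector, each untreated or with 100 ng/ml interferon-gamma for 24 or 48 h. The deposited values are counts of barcodes per probe, 1 column per library, for 770 probes. All 4620 values were whole numbers, and the column totals differed, from 221633 to 441611. How the authors made the counts, and whether positive or negative control probes were used, is not given in the sources used here. Whole numbers do not exclude rounding after a scaling by factors near 1, for example by spiked controls, and such a scaling would change each library's total but no difference measured against the housekeeping genes. Control probes were not used here, so no background was subtracted. In its place the median and 90th percentile of 62 T, NK, B and myeloid marker probes were given per library.

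Libraries were put in groups from the treatment label of each sample, 1 library per group, and the labels carry no replicate numbers. Nothing gave a BTN1A1 level, and since some genes raise a question about the origin of these cultures, they are called the libraries labelled BTN1A1. Counts were scaled by the geometric mean of the 20 panel housekeeping genes (485, 542 and 440 in EV untreated, 24 h and 48 h, and 560, 586 and 407 in the libraries labelled BTN1A1). The 669 genes with at least 20 scaled counts in at least 2 libraries were tested and 101 were left out. Of the 770 probe names 756 matched current symbols in a RefSeq gene table of assembly GRCh38.p14, 6 matched only as synonyms, and 8, such as probes shared by close gene copies, matched neither. The table served for names. Probes of the class I and class II HLA genes can bind related copies, so these genes are uncertain as single genes.

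The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with library sizes set by the housekeeping genes and Benjamini-Hochberg adjustment at 0.05. Each SE given is the absolute log2 difference divided by the square root of the test's F statistic. It restates the test and is not a separate estimate of error. The additive model had vector and condition as terms, and the interaction model had vector, treatment and their product with 24 and 48 h as 2 treated samples. In the latter each untreated arm is 1 library and adds nothing to the residual, which comes from the differences between 24 and 48 h. Each model left 2 residual degrees of freedom, so the tests rest mostly on the spread shared across genes (common dispersion 0.102 and 0.078). Coefficients for interferon-gamma within each vector came from the interaction model and were added after the data had been examined, because the additive model takes a difference in response for noise. The other comparisons, the gene lists and the rule for named genes were fixed before the data were examined. Comparisons of 1 library with another carry no test: values under 20 were raised to 20, genes with at least 20 in 1 of the 2 libraries were compared, and at least 2-fold differences were counted. A log2 difference with 1 library under the floor is a lower bound on its size. The 18 gene lists, with 503 entries, were summarised by members past the threshold over all genes and over the list alone, and by the percentile of their median among 10000 random lists of the same size matched on mean expression in 5 bins.

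The genes named are, per comparison, the 10 largest increases and the 10 largest decreases past the threshold, or, where fewer passed, also the 5 largest that did not pass and had 1 sign in every pair of that comparison, up to 4 members of each list at 48 h, the 5 largest per direction in comparisons of 1 library with another, and a fixed set of interferon pathway, HLA, chemokine and checkpoint genes. Some genes named by this rule are not reported here. Other members of a list given as examples in the text were chosen after their values were seen.

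The tests were tried on simulated data with 200 genes drawn to change, at the dispersion fitted here. Every gene had the common dispersion, and for the additive model each change was the same in both vectors and all conditions it covers. The residual of the data also holds differences in response between the vectors. The shares for interferon-gamma over both vectors therefore do not hold for genes with such a difference, such as GBP1 and CXCL11, which did not pass. For the vector comparison (675 genes tested) edgeR recovered 35.9% of 2-fold, 96.9% of 4-fold and 100% of 16-fold changes; for interferon-gamma at 24 h (668 genes) 29.7%, 80% and 98.4%, and at 48 h (677 genes) 22.2%, 83.6% and 100%. For the interaction (668 genes) it recovered 4.76%, 36.9% and 90.5%. For the response within EV (651 genes) it recovered 6.56%, 54.2% and 100%, and within the libraries labelled BTN1A1 (669 genes) 19.0%, 82.5% and 100%. In these last 2 simulations each change was put into the treated libraries of both vectors, with the same mean counts and dispersion. Each was drawn once with its own changed genes, so the gap between their shares does not measure a difference in power between the vectors. Of 100 simulated unchanged lists 4% lay above the upper bound of the central 95% of random lists, and of 100 lists shifted by 1 log2 unit 92%.

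Alternatives were TMM scaling, DESeq2 1.42.0 with its size factors, limma 3.58.1 on floored log2 values, on log2 of the value plus 1 or plus 10, with trend and robust, and after quantile normalization, edgeR with the robust option, no filter, a minimum of 50, equal medians over the tested genes, a 1.5-fold threshold, and each library left out in turn. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.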

Results

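The series measured messenger RNA in cultures labelled PC3, an established line from a bone metastasis of prostate carcinoma. The nCounter PanCancer IO 360 panel was used, which counts fluorescent barcodes bound to single RNA molecules without amplification. Cells had been transfected with an empty vector (EV) or with an expression vector for BTN1A1, a butyrophilin, a family of membrane proteins related to the B7 ligands of T cells. They were left untreated or given 100 ng/ml interferon-gamma, a T cell cytokine that signals through JAK kinases, for 24 or 48 h. Each of the 6 groups held 1 library, so no comparison has a replicate of its own, and the untreated libraries were labelled 48 h. Total counts were 286341, 441611 and 403510 in the EV libraries (untreated, 24 h, 48 h) and 290097, 297242 and 221633 in the libraries labelled BTN1A1. Of the 770 probes, 0 targeted BTN1A1, so the transfected gene itself was not measured. Markers of T, NK, B and myeloid cells, which PC3 cultures should lack, served as a gauge of background: the median over 62 such probes was 19.0 to 24.5 counts in every library.

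The first question was how PC3 cells with the empty vector respond to interferon-gamma. IDO1, the enzyme that breaks down tryptophan, went from 56 counts to 7385 at 24 h and 10306 at 48 h, and GBP1, an interferon-induced GTPase, from 22 to 3049 and 3691. Over both times together IDO1 rose by a log2 difference of 7.32 (SE 0.77) and GBP1 by 7.26 (SE 0.74). The T cell chemokines CXCL11 and CXCL10 rose by 6.80 (SE 0.72) and 5.30 (SE 0.75), and GBP4 and GBP2 by 5.91 and 5.18. The class II invariant chain CD74 rose by 5.75, HLA-DRA by 5.48, the transcription factor IRF1 by 5.08 and the immunoproteasome subunit PSMB9 by 4.65. The checkpoint ligands CD274 (PD-L1) and PDCD1LG2 (PD-L2) rose by 2.13 (SE 0.60) and 2.26 (SE 0.58). MMP1, a collagenase, fell from 434 counts to 57 and 48, a log2 difference of -3.06 (SE 0.53). The complement component C5 (-1.95), the thromboxane synthase TBXAS1 (-1.88), the early response factor EGR1 (-1.74), the protease receptor F2RL1 (-1.51), the Notch target HES1 (-1.45) and the integrin ITGA1 (-1.40) also fell. Of the 7 decreases, that of MMP1 alone passed without the 24 h EV library, where edgeR gave 61 genes higher and 1 lower. The call for HES1 ended in 9 of 15 other settings and that for ITGA1 in 6. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 76 of 669 genes passed, 69 higher and 7 lower, with an adjusted p of 4.32e-18 for IDO1, 0.00461 for CD274 and 2.59e-07 for MMP1. This test pooled the 24 h and 48 h libraries as 2 treated samples, took the spread of the single untreated library from them, and was added after the data had been seen. Its 24 h library also differs from the untreated one, labelled 48 h, in culture time. All p-values here and below measure only the spread between these libraries, which may be technical. Their size rests mostly on the spread shared across genes, since each model left 2 residual degrees of freedom. A very small p-value therefore does not stand in for replicates.

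By gene group, 13 of 14 measured class I and peptide-loading genes rose in the EV libraries, among them HLA-B (4.10), TAP1 (4.14), HLA-C (2.60) and B2M (2.02), and all 14 rose when adjusted over the list alone. Of 12 class II genes 8 rose, including the invariant-chain protease CTSS (4.44) and HLA-DPB1 (2.30), and 9 when adjusted over the list alone. Of 25 antiviral genes 20 rose, and 21 adjusted over the list alone, with MX1 at 3.04 and ISG15 at 2.02. In the JAK-STAT group 5 of 19 rose, among them STAT2 (1.69), IRF1, IRF9 (2.20) and the feedback inhibitor SOCS1 (2.52). The receptor chains IFNGR1 (0.26) and IFNGR2 (-0.63) and the kinases JAK1 (0.17) and JAK2 (1.04) did not pass, nor did STAT3 (-0.55). Of 9 interferon-inducible chemokines the 3 CXCR3 ligands rose, CXCL9 by 2.57. Of 23 checkpoint and co-stimulatory genes CD274, PDCD1LG2 and IDO1 rose. Of 28 NF-kB and inflammatory genes ICAM1 (3.55), IL15 (2.14) and IL32 (4.24) rose, and of 17 apoptosis genes the death ligand TNFSF10 (2.57) and the inflammatory caspase CASP1 (2.82). The matrix group had 1 of 36 higher (LAMB3, 1.94) and 1 lower (MMP1), the growth factor group 1 of 25 higher (DUSP1, 1.72), and the Notch and Wnt group 1 of 23 lower (HES1). For the JAK-STAT, chemokine, checkpoint, NF-kB, apoptosis, matrix, growth factor and Notch lists the counts adjusted over the list alone were the same numbers. None passed among 28 proliferation, 16 DNA repair, 19 hypoxia and glycolysis and 20 housekeeping genes, nor among 21 T and NK, 23 B and myeloid and 8 endothelial and fibroblast markers, in edgeR's test over all genes or over each list alone.

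Library against library, without a test, 82 genes were at least 2-fold higher and 45 lower in EV at 24 h, and 99 higher and 23 lower at 48 h. The largest increases at 24 h were GBP1 (log2 6.95), IDO1 (6.88), CXCL11 (at least 6.08, its untreated count of 11 being under the floor), GBP4 (5.75) and the cytokine IL32 (4.83), and at 48 h IDO1 (7.67), GBP1 (7.53), CD74 (6.43), HLA-DRA (6.14) and GBP4 (6.06). The largest decreases at 24 h were MMP1 (-3.09), C5 (-2.50), TBXAS1 (-2.44), the cyclin kinase inhibitor CDKN2B (-2.28) and F2RL1 (-1.96), and at 48 h MMP1 (-3.03), EGR1 (-1.59), C5 (-1.55), TBXAS1 (-1.48) and FLT1 (-1.36). The 24 h values also hold culture time, since the untreated library was labelled 48 h. CDKN2B stood at 282 counts untreated, 65 at 24 h and 338 at 48 h. The median log2 difference at 48 h was 2.63 for class I genes, 3.13 for class II genes and 3.08 for antiviral genes, each at percentile 100 of random lists matched on expression. Without the 48 h EV library 48 genes passed in edgeR's test, and with the EV libraries alone 90. Quantile normalization gave 51 genes higher and 14 lower in limma's test, and rescaling to equal medians gave 82 genes at least 2-fold higher and 72 lower at 48 h.

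**Figure D1:**
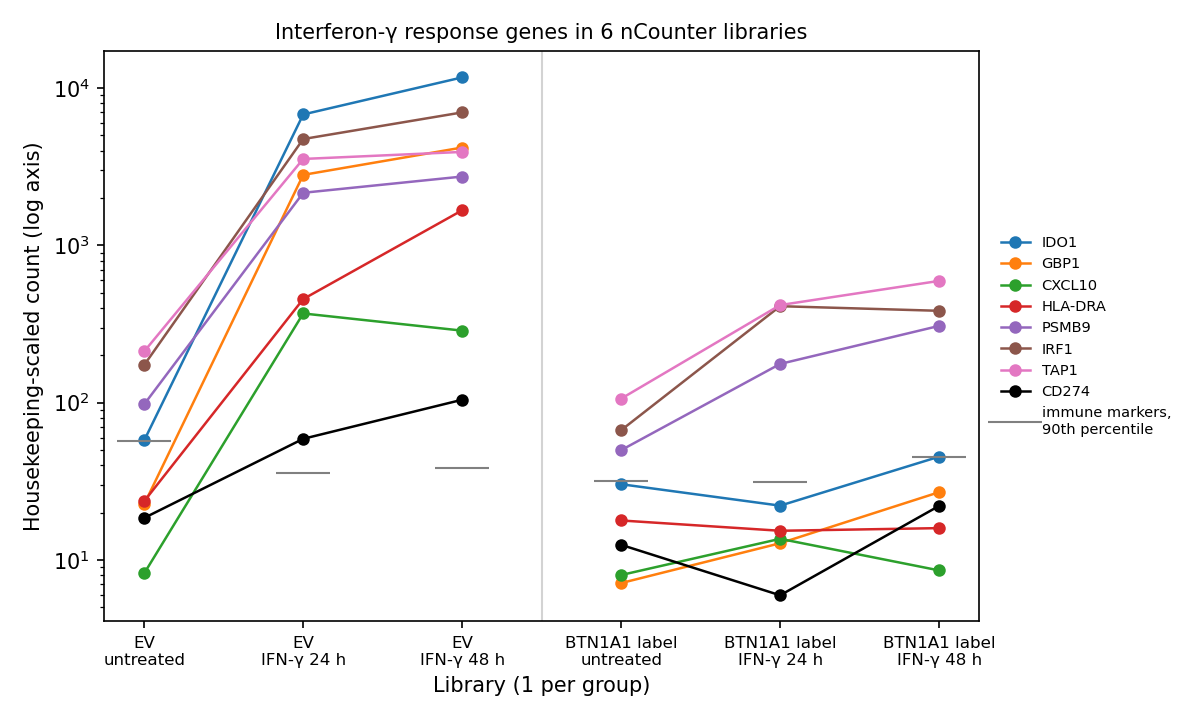
Housekeeping-scaled counts (log axis) of 8 interferon-gamma response genes in the 6 libraries, 1 point per library with no error bar because each group holds 1 library; lines join libraries of 1 vector and grey bars mark the 90th percentile of 62 immune marker probes. IDO1 reaches 10306 counts before scaling in the 48 h EV library and 37 in the 48 h library labelled BTN1A1.

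The same question was asked of the libraries labelled BTN1A1. IRF1 went from 75 counts to 482 at 24 h and 313 at 48 h, and the peptide transporter TAP1 from 119 to 490 and 485. Over both times IRF1 rose by a log2 difference of 2.57 (SE 0.59), PSMB9 by 2.27 (SE 0.56) and TAP1 by 2.25 (SE 0.56). The antiviral IFIT3 rose by 2.07 (SE 0.59), and the partner proteins PARP9 and DTX3L by 2.06 (SE 0.56) and 1.96 (SE 0.54). IDO1, at 34, 26 and 37 counts, had a log2 difference of 0.13 (SE 0.59), and CD274, at 14, 7 and 18 counts, of 0.08 (SE 0.69); neither passed. HLA-B (0.16), HLA-C (0.54), B2M (0.88), HLA-DRA (-0.19), CD74 (0.75), CXCL9 (0.73), CXCL10 (0.49), CXCL11 (1.04), SOCS1 (0.08), STAT2 (0.28), STAT3 (0.62), PDCD1LG2 (0.43), IFNGR1 (-0.25), IFNGR2 (-0.14), JAK1 (-0.16) and JAK2 (-0.17) did not pass either. Of 669 genes 7 passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p 0.00913 for IRF1, 0.0467 for IFIT3), again pooling both times and added after the data had been seen. Of the genes that did not pass and rose at both times, the largest increases were the apolipoprotein APOL6 (1.92), HLA-E (1.85), IRF8 (1.65), SAMD9 (1.47) and TAPBPL (1.25). The largest decreases with 1 sign at both times, none past the threshold, were the stress factor ATF3 (-0.85), HERC6 (-0.69), PCK2 (-0.68), NFIL3 (-0.66) and PVR (-0.62).

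By group these were 2 of 19 JAK-STAT genes (3 adjusted over the list alone), 2 of 14 class I genes (3 over the list alone) and 1 of 25 antiviral genes (1 over the list alone). In each of the other 15 lists 0 members passed, over all genes or over the list alone. Library against library, 17 genes were at least 2-fold higher and 18 lower at 24 h, and 31 higher and 0 lower at 48 h. The largest increases were IRF1 (2.62), TAP1 (1.98), PSMB9 (1.82), PARP9 (1.77) and DTX3L (1.77) at 24 h. At 48 h the largest included PSMB9 (2.62), IRF1 (2.52), TAP1 (2.49) and APOL6 (at least 2.46). The largest decreases at 24 h were ATF3 (-1.99), PCK2 (-1.72), WNT2B (-1.51), HES1 (-1.46) and PDGFA (-1.39). Here too the 24 h values also hold culture time. The immune marker background moved with these counts: its scaled median was 16.9 in the untreated library, 16.6 at 24 h and 25.7 at 48 h. With a floor of 50 in place of 20 the 48 h count was 12 higher and 0 lower. Rescaling to equal medians gave 28 higher and 9 lower at 24 h. The 7 calls became 1 without the 48 h library labelled BTN1A1, 3 without either treated EV library and 4 in DESeq2. They became 0 with TMM scaling (23 at an unadjusted p under 0.05), with a minimum of 50 (15) and in limma on floored values (12) or after quantile normalization (33).

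Over both vectors, with the 2 libraries of a condition as the only repeats, 6 genes rose after 48 h. Among them were TAP1 (log2 difference 3.24, SE 0.55), IFIT3 (2.84, SE 0.41), PARP9 (2.75, SE 0.41), DTX3L (2.63, SE 0.38) and the NK cell ligand HLA-E (2.55, SE 0.41), with adjusted p from 0.0366 to 0.0426 over the 6 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Larger mean differences that did not pass belonged to genes that differed between the vectors, such as GBP1 (4.78, SE 1.53), CXCL11 (4.56, SE 1.61), CD74 (3.45, SE 1.22), HLA-DRA (2.98, SE 1.42), CXCL10 (2.89, SE 1.19) and IDO1 (2.78, SE 1.71). IRF1 (3.83, SE 0.68) and PSMB9 (3.56, SE 0.66) came close to the threshold, with an edgeR adjusted p of 0.0532 for IRF1. CD274 stood at 1.74 (SE 0.61), PDCD1LG2 at 1.39, HLA-B at 2.05, HLA-C at 1.74, B2M at 1.65 and CXCL9 at 1.66. Smaller differences were those of STAT2 at 1.24, SOCS1 at 0.95, JAK2 at 0.56, STAT3 at 0.33, IFNGR1 at 0.20, JAK1 at 0.03 and IFNGR2 at -0.16. The largest decreases that had 1 sign in both vectors were TBXAS1 (-0.92), EGR1 (-0.91), CCNE1 (-0.67), FLT1 (-0.64) and RIPK3 (-0.63), none of which passed. By group, 2 of 14 class I genes (12 adjusted over the list alone), 1 of 25 antiviral genes (9 over the list alone) and 1 of 19 JAK-STAT genes (3 over the list alone) rose. In the other 15 lists 0 members passed either way. Their largest values included ICAM1 (2.02), CASP1 (1.97), IL15 (1.99), LAMB3 (1.15), HEY1 (0.82), KDR (0.75), VEGFC (0.70), NBN (0.70), KLRK1 (1.14), LYZ (0.92), PECAM1 (0.50) and TFRC (-0.58).

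After 24 h 0 of 669 genes passed the same edgeR test, with 58 at an unadjusted p under 0.05; DESeq2 called 20 (17 higher, 3 lower) and limma 0. The largest mean increases were CXCL11 (4.18, SE 1.67) and GBP1 (4.08). The largest with 1 sign in both vectors were IRF1 (3.51, SE 0.66), PSMB9 (3.05), TAP1 (2.95), GBP4 (2.53) and APOL6 (2.38). CXCL10 stood at 3.28, CXCL9 at 2.07, IDO1 at 1.95, CD74 at 1.82, SOCS1 at 1.79 and HLA-DRA at 1.55. MMP1 had the largest mean decrease (-2.13), and the largest with 1 sign in both vectors were HES1 (-1.61), TBXAS1 (-1.54), WNT2B (-1.48), PCK2 (-1.35) and FLT1 (-1.32). PDCD1LG2 stood at 1.28, B2M at 1.15, HLA-C at 1.12 and HLA-B at 1.11. CD274 stood at 0.64, STAT2 at 0.56, JAK2 at 0.26, JAK1 at -0.03, STAT3 at -0.08, IFNGR1 at -0.25 and IFNGR2 at -0.66. In every list 0 members passed over all genes, while 10 of 14 class I, 3 of 25 antiviral and 2 of 19 JAK-STAT genes passed when adjusted over the list alone and 0 in the other 15 lists. This contrast also holds culture time, since the untreated libraries were labelled 48 h. The residual of this fit holds any difference between the vectors in their response, and the counts moved with the libraries. At 24 h, 87 genes passed without the untreated library labelled BTN1A1, 11 without its 24 h library, 7 without the 24 h EV library and 9 without the untreated EV library. At 48 h the counts were 95, 14, 27 and 9 without the same libraries, and 0 without either 48 h library. TMM scaling also gave 0 at 48 h (47 at an unadjusted p under 0.05), as did limma on floored values (44), and DESeq2 gave 22.

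Whether the response to interferon-gamma differed between the vectors was tested as an interaction. Some genes, among them STAT3, raise a question about the origin of the cultures labelled BTN1A1. A difference between the vectors is therefore also one between cultures that may differ in origin. IDO1 responded less in the libraries labelled BTN1A1 than in EV by a log2 difference of -7.19 (SE 0.88), GBP1 by -5.84 (SE 0.98), CXCL11 by -5.76 (SE 1.03) and HLA-DRA by -5.67 (SE 0.84). The differences were -5.25 (SE 0.81) for GBP4, -5.09 (SE 0.80) for GBP2, -5.00 (SE 0.79) for CD74, -4.80 (SE 1.06) for CXCL10, -4.24 (SE 0.76) for CTSS and -4.12 (SE 0.75) for IL32. HLA-B (-3.94) and IRF1 (-2.51) also differed, though of 14 other settings the call for IRF1 ended in 5 and that for HLA-B in 1. MMP1 (3.85, SE 0.97) and IRF8, an interferon-inducible transcription factor (2.90, SE 0.94), differed the other way. MMP1 fell in EV and stood at 7, 9 and 12 counts in the libraries labelled BTN1A1. IRF8 stood at 18, 6 and 9 counts in EV, at the background, and at 58, 167 and 149 in the libraries labelled BTN1A1. The call for IRF8 ended in 8 of 14 other settings, and without either treated EV library 0 genes passed in this direction. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 30 of 669 genes passed, 2 with the more positive response in the libraries labelled BTN1A1 and 28 with the more positive response in EV. The edgeR adjusted p was 6.61e-13 for IDO1, 0.0214 for IRF1 and 0.0462 for IRF8. Each untreated arm of this model is 1 library, so its spread is taken from the 24 h and 48 h libraries, which count as repeats. The differences for CD274 (-2.05, SE 0.91), PDCD1LG2 (-1.83), HLA-C (-2.07), B2M (-1.13), TAP1 (-1.89), STAT2 (-1.41), STAT3 (1.17), SOCS1 (-2.44), CXCL9 (-1.84), JAK1 (-0.34), JAK2 (-1.22), IFNGR1 (-0.50) and IFNGR2 (0.49) did not pass. Nor did the next largest positive ones with 1 sign at both times, C5 (2.14), MRC1 (2.09), ITGB8 (2.09), PRKX (1.87) and OLFML2B (1.80).

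Of 12 class II genes 6 differed (8 adjusted over the list alone), of 14 class I genes 4 (8 over the list alone), of 25 antiviral genes 9 (15 over the list alone), of 9 chemokines 2 (2 over the list alone) and of 28 NF-kB genes ICAM1 and IL32 (2 over the list alone), all with the larger response in EV. In the JAK-STAT list IRF8 and IRF1 differed, in the checkpoint list IDO1, in the matrix list MMP1 and in the growth factor list DUSP1 (-2.14). Adjusting over each list alone left these counts as they were, and in the remaining 9 lists 0 members passed either way. Per time, without a test, the median response difference was -1.56 at 24 h and -1.65 at 48 h for class I, -1.42 and -2.80 for class II, and -2.23 and -2.44 for antiviral genes, at percentiles of 0 to 0.02 among matched random lists. For JAK-STAT genes the medians were -0.40 and -0.35, for NF-kB genes -0.39 and -0.12, for chemokines 0.10 and -0.02, and for checkpoint genes 0 and 0.19. Of these, NF-kB genes at both times (percentiles 1.76 and 1.37) and JAK-STAT genes (1.80) and chemokines (2.495) at 48 h lay outside the central 95% of random lists. The NF-kB median at 48 h was 0.22 without a floor, on log2 of the value plus 1, so its sign rests on the floor. The chemokine median rests on members near the floor: with a floor of 50 it was -2.54 and -1.84, and over the 3 members changed at least 2-fold -4.21 and -3.84. They were -0.01 and -0.05 for apoptosis genes, -0.08 and 0.02 for proliferation, -0.62 and 0.11 for DNA repair, and -0.14 and 0.00 for hypoxia and glycolysis. Matrix genes had medians of -0.01 and 0.46 (percentile 98.3, also outside), Notch and Wnt genes 0.28 and 0.37, growth factor genes 0.02 and 0.23, T and NK markers 0.12 and 0.70, B and myeloid markers 0.46 and 0.62, endothelial and fibroblast markers 0.11 and 0.77, and housekeeping genes -0.08 and 0.01. The immune marker probes that gauge background had scaled medians of 25.2, 18.9 and 21.6 in EV (untreated, 24 h, 48 h) against the 16.9, 16.6 and 25.7 given above. At 24 h the positive medians of the T and NK and of the B and myeloid markers come from a fall in EV (-0.21 and -0.47), with medians of 0 in the libraries labelled BTN1A1. Across 669 genes, which are not independent replicates, the responses of the vectors correlated with Pearson's r of 0.25 at 24 h and 0.29 at 48 h (Spearman's rho 0.14 and 0.01). Without the 48 h EV library 14 genes passed; quantile normalization with limma gave 18, and without either untreated library the interaction could not be fitted.

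**Figure D2:**
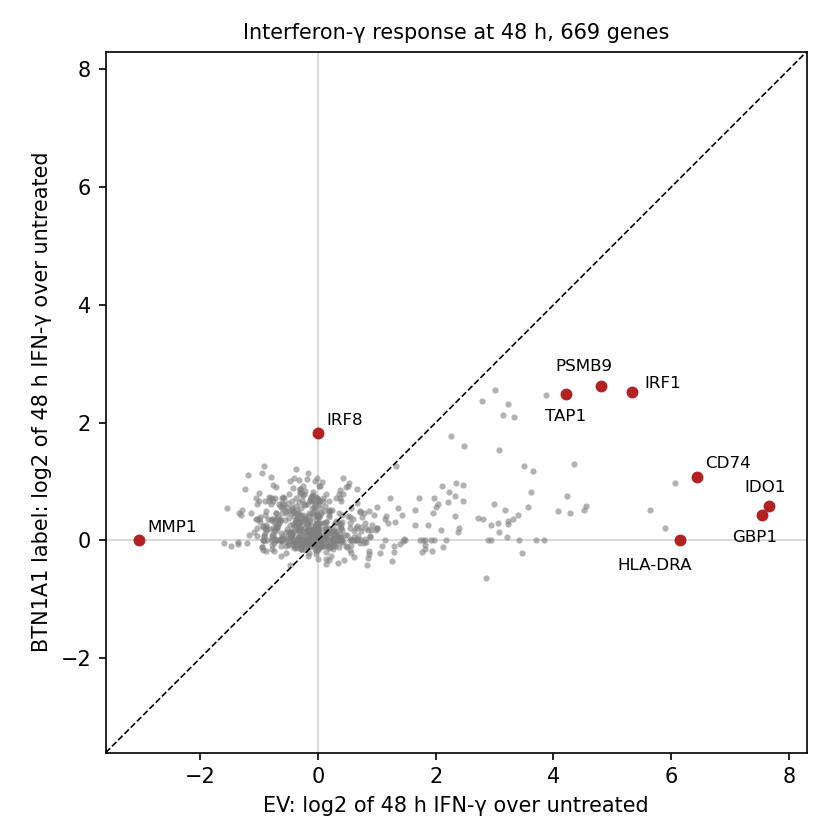
Log2 difference between 48 h of interferon-gamma and no treatment in EV (horizontal) and in the libraries labelled BTN1A1 (vertical), 1 point per gene for 669 genes with values under 20 raised to 20 and 1 library per group; the dashed line marks equal responses. IRF1 lies at 5.33 in EV and 2.52 in the libraries labelled BTN1A1, and IDO1 at 7.67 and 0.58.

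The libraries labelled BTN1A1 were then compared with EV over the 3 conditions. Vector and culture cannot be separated in this comparison, and the cultures may differ in origin. DKK1, a secreted Wnt inhibitor, stood at 14004, 9203 and 13264 counts in EV and at 21, 23 and 15 in the libraries labelled BTN1A1, a fitted log2 difference of -9.33 (SE 0.37). The latter counts lie at the background, so the fitted size is a ratio to background. The AP-1 factor FOSL1 (-7.75, SE 0.35), the matrix protein THBS1 (-6.76, SE 0.43), the antiviral OAS2 (-6.72, SE 0.43) and IDO1 (-6.51, SE 1.75) were also lower. So were the immunoproteasome subunit PSMB8 (-6.46, SE 0.60), the cadherin CDH11 (-6.37, SE 0.38), the hyaluronan receptor CD44 (-6.19, SE 0.44), GBP1 (-6.17, SE 1.25) and the Toll-like receptor adaptor MYD88 (-6.13, SE 0.73). Several of these also stood near the background in the libraries labelled BTN1A1. Untreated, THBS1 had 19 counts there and CD44 28. At 24 and 48 h IDO1 had 26 and 37, GBP1 15 and 22, and PSMB8 23 and 17. The fitted sizes of these genes are likewise in part ratios to background. Cyclin D2 (CCND2) was higher by 6.35 (SE 0.33), STAT3 by 4.83 (SE 0.42), and the amino acid transaminase BCAT1 by 4.08 (SE 0.34). Also higher were ID4 by 3.89 (SE 0.36), the cancer-testis gene MAGEB2 by 3.77 (SE 0.34), the adhesion molecule NCAM1 by 3.58 (SE 0.39), arginase ARG2 by 3.50 (SE 0.34), the receptor kinase KIT by 3.42 (SE 0.39) and GPR160 by 3.37 (SE 0.35). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 283 of 669 genes passed, 78 higher and 205 lower, with an adjusted p of 5.79e-06 for DKK1 and 1.75e-05 for CCND2. These 19 genes all differed in the same direction in each of the 3 conditions. The split depends on the scaling: TMM gave 117 higher and 161 lower, DESeq2 144 and 189, and quantile normalization with limma 176 and 113. Against housekeeping scaling every log2 difference rises by 0.39 with TMM, 0.37 with DESeq2's size factors, 0.54 with total counts and 1.07 with equal medians.

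Over the 3 conditions antiviral, class I and part of the class II genes were lower in the libraries labelled BTN1A1. Of 25 antiviral genes 22 were lower and 0 higher (22 lower over the list alone; median -3.12), with ISG15 at -5.52 and MX1 at -4.41. Of 14 class I genes 11 were lower (12 over the list alone; median -2.03), with B2M at -2.92 and TAP1 at -2.30, while HLA-B (-1.13) and HLA-C (-0.39) did not pass. Of 12 class II genes 5 were lower (5 over the list alone; median -1.34), with HLA-DRA at -4.26 and CD74 at -3.94, and of 28 NF-kB and inflammatory genes 17 (18 over the list alone; median -1.23), with IL18 at -5.92, CXCL1 at -4.03, CXCL8 at -3.39 and IL6 at -1.78. These 4 medians stay below 0 when shifted by the 0.39, 0.37, 0.54 or 1.07 given above. Of 9 chemokines 4 were lower (4 over the list alone), among them CXCL11 (-5.44), CXCL10 (-3.74) and CXCL9 (-3.28), and of 23 checkpoint genes 9 were lower (10 over the list alone), including PDCD1LG2 (-2.20) and CD274 (-2.06). The calls for HLA-DRA, CD74 and CXCL10 ended in 7 of 16 other settings each and that for CXCL11 in 6. Those for CD274 and IDO1 ended in 5 each and that for GBP1 in 3, while those for B2M, TAP1 and PDCD1LG2 held in all 16. Of 19 JAK-STAT genes 4 were higher and 9 lower (4 and 9 over the list alone). IFNGR1 (1.65) and STAT3 were higher, and IRF1 (-3.09), SOCS1 (-2.62), STAT2 (-2.23) and JAK2 (-1.81) lower. JAK1 (0.06) and IFNGR2 (-0.63) did not pass. Because these libraries include 2 treated ones per vector, the values hold the difference in response too. In the untreated libraries alone the antiviral median was -1.31 (15 of 25 at least 2-fold lower, 1 higher) and the class I median -0.83 (4 lower, 1 higher), a value smaller than the shift of 1.07 given above. The class II median there was -0.30, with 0 of 12 genes at least 2-fold lower and 2 higher. Class II genes such as CD74 (44 counts) and HLA-DRA (23 counts) lay near the background in the untreated EV library. A lower value could hardly be seen for them there, so the untreated libraries cannot tell whether they differ without treatment.

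Of 36 matrix and mesenchymal genes 4 were higher and 16 lower (5 and 16 over the list alone), with ZEB2 at 2.93, COL6A3 at -4.92, CDH1 at -2.69 and the epithelial marker EPCAM at -2.55. Of 25 growth factor genes 5 were higher and 8 lower (6 and 9 over the list alone), with EGFR at -2.94. Of 23 Notch and Wnt genes 7 were higher and 5 lower (7 and 6 over the list alone), with HES1 at 1.02 and JAG1 at -4.26. Of 28 proliferation genes 6 were higher and 4 lower (6 and 4 over the list alone), with MYC at 0.86 and CCND1 at -2.81. Of 16 DNA repair genes 5 were higher and 3 lower (5 and 3 over the list alone). Of 19 hypoxia and glycolysis genes 1 was higher (LDHB, 1.46) and 7 lower (1 and 7 over the list alone), with VEGFC at -4.62 and LDHA at -1.73. Of 17 apoptosis genes 3 were higher and 6 lower (3 and 6 over the list alone), with BCL2 at 1.41 and CASP8 at -2.44. Among 20 housekeeping genes 3 were higher and 4 lower (2 and 2 over the list alone), with TFRC at -1.61, so the scaling genes were not constant between the vectors. Of 21 T and NK markers CD3G (1.57) was higher and LAG3 (-0.91) lower (0 and 0 over the list alone). Of 23 B and myeloid markers CD68 (-2.69) was lower (1 over the list alone), and of 8 endothelial and fibroblast markers PECAM1 (-1.52) and COL6A3 were lower (2 over the list alone). LAG3 turns positive when medians are equalised. The 5 most abundant genes took 21.4 to 23.3% of counts in EV and 35.7 to 40.1% in the libraries labelled BTN1A1.

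Library against library, 76 genes were at least 2-fold higher and 187 lower untreated, 58 and 203 at 24 h, and 88 and 190 at 48 h; with equal medians these became 170 and 98, 261 and 117, and 222 and 136. CCND2 (6.10 untreated, at least 6.28 at 24 h, at least 6.20 at 48 h) and STAT3 (4.05, at least 4.66, at least 4.77) were among the 5 largest increases in each condition. BCAT1 (4.06 and at least 4.44) was among them untreated and at 24 h, GPR160 (3.90) untreated and MAGEB2 (4.27) at 24 h. At 48 h ARG2 (4.08), KIT (at least 3.85) and the mTOR-binding DEPTOR (at least 3.79) completed it. DKK1 had the largest decrease in each condition, at -9.49, -8.73 and -9.56, each a lower bound on its size, and FOSL1 stood at -7.19, -8.22 and -7.85. The other large decreases were THBS1 (-6.37, a lower bound), CD44 (-5.93) and DUSP5 (-5.76) untreated, and IDO1 (-8.26 and -8.01), PSMB8 (-7.10, a lower bound, and -7.34) and GBP1 (-7.13, a lower bound, and -7.28) at 24 and 48 h. Across 669 genes the difference correlated between untreated and 24 h with Pearson's r of 0.80 (Spearman's rho 0.75), between untreated and 48 h with 0.79 (0.72), and between 24 h and 48 h with 0.94 (0.86). These pairs share no library.

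**Figure D3:**
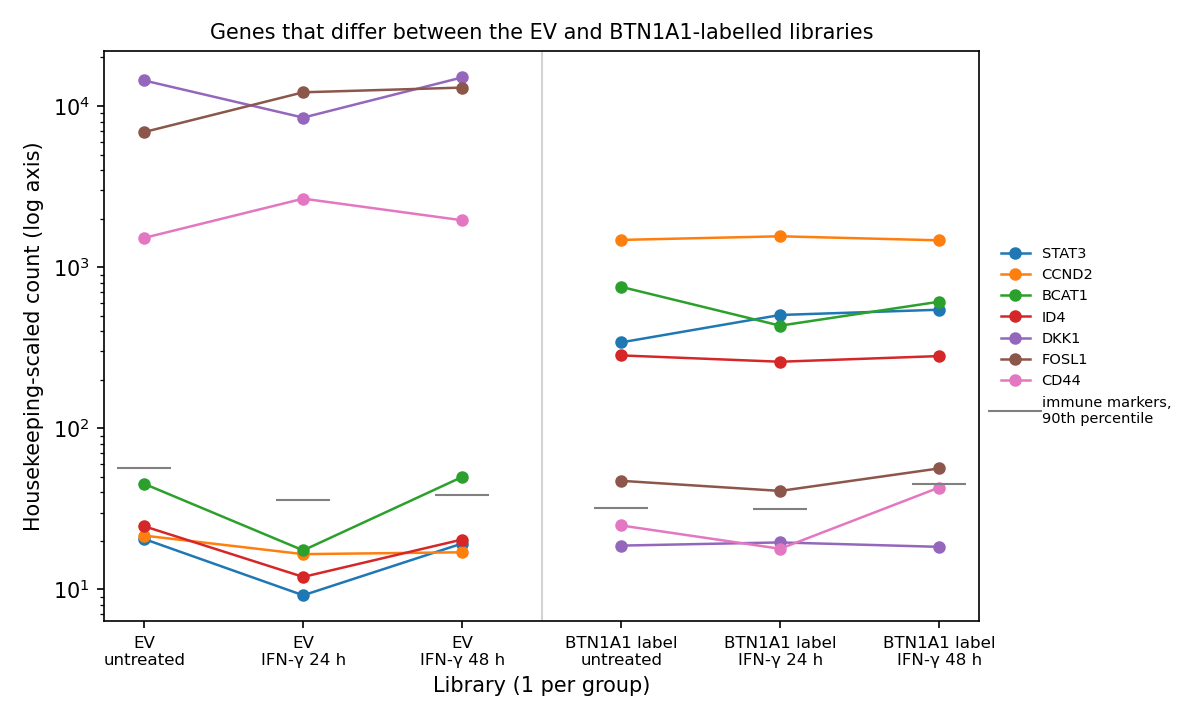
Housekeeping-scaled counts (log axis) of 7 genes in the 6 libraries, 1 point per library with no error bar because each group holds 1 library; lines join libraries of 1 vector and grey bars mark the 90th percentile of 62 immune marker probes. CCND2, STAT3, BCAT1 and ID4 are higher, and DKK1, FOSL1 and CD44 lower, in all 3 libraries labelled BTN1A1.

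The 48 h libraries were last compared with the 24 h libraries of the same vector, without a test. In EV 33 genes were at least 2-fold higher and 7 lower at 48 h, among them the stress factor ATF3 (2.86), the EGFR ligand AREG (2.79), CDKN2B (2.68), the mitochondrial enzyme PCK2 (2.63) and HLA-DPB1 (2.48) higher. IL32 (-1.60), SOCS1 (-1.30), cyclin E1 (CCNE1, -1.30), the helicase HELLS (-1.08) and COL6A3 (-1.05) had the largest decreases. Class II genes as a group were higher at 48 h in EV, with 8 of 12 at least 2-fold higher and 0 lower. In the libraries labelled BTN1A1 45 genes were higher and 5 lower, among them ATF3 (1.77), APOL6 (1.70), WNT2B (1.70), IL15 (1.67) and PCK2 (1.65) higher. The transferrin receptor TFRC (-1.72), H2AFX (-1.40), HMGB1 (-1.31), RIPK1 (-1.30) and LDHA (-1.17) had the largest decreases. With equal medians the counts were 22 and 13 in EV and 6 and 44 in the libraries labelled BTN1A1, so the split of the latter rests on the scaling, and TFRC is itself one of the housekeeping genes.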

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

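All tests of explanations in this part were chosen after the result was seen; the interaction itself was planned. It differed between the vectors for 30 genes by its own test. Against the EV response, the response in the libraries labelled BTN1A1 was smaller for IDO1 (log2 difference -7.19), GBP1 (-5.84), CXCL11 (-5.76), HLA-DRA (-5.67), GBP4 (-5.25), GBP2 (-5.09), CD74 (-5.00), CXCL10 (-4.80), CTSS (-4.24) and IL32 (-4.12). It was more positive for IRF8 (2.90) and for MMP1 (3.85), which fell in EV and stood at the background, 7, 9 and 12 counts, in the libraries labelled BTN1A1. These 2 rest on little: the call for IRF8, at the background in EV, ended in 8 of 14 other settings, and without either treated EV library 0 genes passed in this direction.

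A lack of active interferon-gamma in these cultures would leave the genes raised in EV without a response there. The median log2 response of those 69 genes was 0.44, with 61 above 0, against 0.09 for the other genes and at most 0.26 for random lists. Those lists were matched on the mean over all libraries, not on the level in these cultures. In the same fit T and NK markers had a median of 0.22, B and myeloid markers 0.32 and endothelial and fibroblast markers 0.53. The list median therefore cannot decide. Single genes did rise well above the background, such as IRF1 from 75 counts to 482 and 313. Signal lost under the background could hide a response, but 11 of the 28 genes with the smaller response had at least 50 scaled counts in the untreated library labelled BTN1A1, and their median difference was -3.03 (SD 0.61). Those 11 were picked for differing. All 22 genes raised in EV and measured this way had a median of -2.10, with 22 lower. These 22 were in turn picked for a high response in EV, which pushes the difference below 0, so the count of 22 was partly fixed in advance. Their median response was 2.65 in EV and 0.48 in the libraries labelled BTN1A1. An effect of BTN1A1 on the response could not be tested, because 0 pairs of libraries differ in the vector but not in the culture. The cells of the 2 cultures may also differ in origin, as weighed among the other observations. The difference in response can therefore not be credited to BTN1A1.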

How the results depend on the processing

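Of the log2 differences of named genes under other settings 3634 kept their sign and side of the threshold, 143 came to pass, 205 ceased to and 97 changed sign while passing under neither setting. Of the counts, medians and correlations 199 stayed within their bounds and 72 moved, but the direction turned in 8 splits into higher and lower genes and in 20 list medians. The splits were those of the vector over 3 conditions after quantile normalization (176 higher, 113 lower), of the vector in each condition, of the libraries labelled BTN1A1 at 24 h (28 and 9) and of their 48 against 24 h (6 and 44) with equal medians, of the libraries labelled BTN1A1 at 24 h with a floor of 50 (15 and 12), and of EV at 24 h at 1.5-fold (120 and 131). The count for the vector over 3 conditions stayed within 1.5 times 283 under every alternative and left-out library (215 to 333). Leaving out each library gave 0 to 87 genes for interferon-gamma at 24 h over both vectors, 0 to 95 at 48 h (the highest of each without the untreated library labelled BTN1A1), 14 to 37 for the interaction, 48 to 91 within EV and 1 to 9 within the libraries labelled BTN1A1. A fit left with 1 library in an arm assumes that it varies like the others, and the interaction without an untreated library could not be fitted. At 24 h (main count 0) DESeq2 gave 20, edgeR with the robust option, added after seeing the data, 3, and limma with trend and robust 2. At 48 h (6) DESeq2 gave 22 and no filter 11, while TMM, a minimum of 50, quantile normalization and limma on floored values, on log2 of the value plus 1 or plus 10 gave 0. The interaction (30) gave 18 after quantile normalization. The response within the libraries labelled BTN1A1 (7) gave 4 in DESeq2 and 0 with TMM, a minimum of 50, floored limma and quantile normalization. At 1.5-fold, which by construction admits more genes, the comparisons of 1 library with another counted 251 (EV 24 h), 249 (EV 48 h), 119 and 123 (libraries labelled BTN1A1, 24 and 48 h), 404 (vector, untreated), 149 (EV, 48 against 24 h) and 218 (libraries labelled BTN1A1, 48 against 24 h). For the libraries labelled BTN1A1 at 48 h (31) the count was 59 without a floor, 12 with a floor of 50 and 17 with equal medians, and for 48 against 24 h (50) it was 89 without a floor and 23 with a floor of 50. The median response difference of lists also moved. With a floor of 50 it was -0.52 for NF-kB and 0.21 for matrix genes at 48 h, 0.48 for T and NK markers and -0.79 for endothelial and fibroblast markers at 24 h, and -0.57 and -0.73 for B and myeloid markers, whose members lie near the floor. With equal medians it was at 24 h 0.012 for JAK-STAT, -1.15 for class I, 0.19 for checkpoint, -0.14 for NF-kB, 0.46 for apoptosis, 0.29 for proliferation, -0.21 for DNA repair, 0.26 for hypoxia, 0.53 for T and NK and 0.33 for housekeeping genes, and at 48 h 0.064 for Notch and Wnt and 0.48 for B and myeloid genes. Over members changed at least 2-fold, a smaller set, it was at 24 and 48 h -1.87 and -1.62 for JAK-STAT, -2.12 and -2.24 for checkpoint, -3.39 and -2.89 for NF-kB, -2.29 and -2.47 for apoptosis and death receptors, 3.09 and 3.03 for matrix (1 gene) and, at 48 h, 1.16 for Notch and Wnt genes (1 gene). Where no construction is named, the cause was not tested. Class II and antiviral medians, and class I at 48 h, stayed within their bootstrap intervals. The housekeeping alternative planned for the comparisons without a test equals the setting used. Beyond the matching of the vectors by condition in the additive model, no paired analysis was possible, because the labels carry no replicate numbers and each group holds 1 library. Depth limits genes near 20 counts, where background makes up most of the value.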

Other observations

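Tests of explanations in this part were chosen after the result was seen, except the count of other splits, which was planned. ATF3 and PCK2 were lowest at 24 h among the libraries labelled BTN1A1 and higher at 48 h than at 24 h in both vectors, 1 library each. ATF3, a transcription factor of the stress response, stood at 1063 counts untreated, 280 at 24 h and 665 at 48 h in the libraries labelled BTN1A1, and at 69, 117 and 690 in EV. PCK2, which makes phosphoenolpyruvate in mitochondria, stood at 717, 227 and 494 counts and at 157, 100 and 501. TFRC, the transferrin receptor, went the other way: it stood at 545, 1664 and 352 counts in the libraries labelled BTN1A1 and at 2546, 2477 and 1256 in EV. Ribosomal RPL23 and RPL7A were among the 5 most abundant genes in each library labelled BTN1A1 and in none of the EV libraries.

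Proliferation genes were highest at 24 h: 18 of 28 in EV and 17 of 28 in the libraries labelled BTN1A1 had their highest value there, against 18.7% and 16.6% of all genes. Culture time and an early effect of interferon-gamma cannot be told apart, because 0 untreated libraries were labelled 24 h.

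STAT3 is a gene that PC3 cells are known to have lost, as background knowledge. It stood at 20, 10 and 17 counts in EV and at 383, 593 and 444 in the libraries labelled BTN1A1. A difference in scaling or depth is argued against by the lowest log2 difference of STAT3 over 5 scalings, 4.83 (SE 0.42), and EV-like cells mixed with others by the 6 of 48 abundant EV genes that lay under 5% of EV in all 3 libraries labelled BTN1A1, with DKK1 at the background and so at no more than 0.231%. If PC3 cells have lost the gene, a BTN1A1 vector could not raise it. On that background knowledge the STAT3 counts in all 3 libraries labelled BTN1A1 argue against an effect of the vector on PC3 cells, for this gene. For the other genes cells of another origin and an effect of the BTN1A1 vector cannot be told apart. The reason is that 0 libraries have a measure of cell identity that was not chosen for this pattern. In addition, 0 pairs of libraries differ in the vector but not in the culture. No level of BTN1A1 was measured.

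Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, namely itself with 283, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.05. Every other split also mixes the vectors, so the vector difference enters its residual and keeps genes from passing. The 0 of the others therefore lends no support.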
